A study of Mus musculus with 8 samples.

How the data were processed

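Single-nucleus ATAC-seq, which reads open chromatin as the sites where a transposase cuts DNA, was measured in the livers of 8 C57BL/6 mice aged 24 weeks. Per the labels, the mice had eaten a Western diet for 12 weeks and then stayed on it for 4 weeks of weekly injections of vehicle or ADI-PEG 20, a pegylated arginine deiminase that breaks down circulating arginine. The mice were Becn1+/+ or Becn1+/- littermates, Becn1 coding for the autophagy protein Beclin 1, which gives 4 groups of 2 libraries, 1 mouse per library, with 5000 nuclei targeted per library. Sex, litter and processing date are not in the labels, and the libraries carry no numbers that pair them across groups.

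The deposited values were counts of transposase cut sites per called peak and barcode, with 1 peak list and 1 matrix per library. The submitters' processing notes name Cell Ranger ATAC, Cell Ranger and MACS2 2.1.0 with mm10 (GRCm38), and the matrix headers give software version 1.2.0. The notes do not say which tool called the peaks. In each library 92.3% to 94.6% of the values were even, as when both ends of a fragment fall in 1 peak. Peaks were called separately in each library, so a region without a call has no value, not a 0.

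The 8 peak lists were merged with bedtools 2.31.1 into 214013 regions, of which 89741 (41.9%) held a call from every library. These shared regions covered 244 Mb of 303 Mb and held 94.6% to 99.0% of each library's counts. Gene accessibility was the sum of counts in shared regions that overlap the gene body or the 2 kb upstream of its start, from GENCODE M21, for 16556 of 21933 protein-coding genes; 27 repeated symbols were left out. Because 5017 of the shared regions (5.59%) overlap the windows of more than 1 gene, neighbouring genes can carry the same counts. For many of the named genes concerned this is marked in the text. Promoter windows, from 2 kb upstream to 500 bp downstream of the start, held a shared region for 14347 genes.

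Barcodes with at least 1000 counts were kept as nuclei, 40763 in all; 32 barcodes of Becn1+/+ vehicle replicate 1 and 8 of Becn1+/+ ADI-PEG 20 replicate 1 were removed. Nuclei of all libraries were clustered together on shared regions by TF-IDF, singular value decomposition (scikit-learn 1.9.0, 30 components, of which 2 to 30 were used because the first had r = 0.982 with log10 depth), 15 nearest neighbours and Leiden at resolution 1.0 (leidenalg 0.10.2, python-igraph 0.11.9, seed 1), without batch integration. A cluster was named "-like" from fixed marker lists when its mean marker z-score led the next class by 0.2 and at least 3 markers were detected at 5 CPM and 1.5 times the median cluster; clusters with a mean doublet score above 0.8 stayed unnamed. Doublets were simulated per library with 50 neighbours and the top 5% of nuclei marked, but not removed in the primary fits.

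Counts were summed per library and class. Tests used edgeR 4.0.16 (TMM, filterByExpr with a minimum count of 10, robust quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Treatment and genotype were fitted together for effects over both levels of the other factor. A fit with 1 mean per group gave the contrasts within a genotype or treatment and their interaction. All p-values but those of camera, described below, measure the spread between these 8 samples, with 2 per group. DESeq2 1.42.0 was run on the same counts. Log2 fold changes are given ± SE with n = 2 libraries per group, or n = 4 per arm for effects over both levels. The SE was derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F. It rests on the spread fitted over all 8 libraries and moderated across genes, not on the compared libraries alone. CPM of a gene or region are counts scaled to the TMM-adjusted total of the tested genes or regions of the class in each library. CPM of summed markers are scaled to the unadjusted total over genes.

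The 23 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, camera with an estimated correlation, and fry. Camera compares the genes of a list with the other genes. At the preset correlation its p-values rest on an assumed value and do not measure the spread between animals. The lists were urea cycle and arginine metabolism, integrated stress response and amino acid deprivation, fatty acid oxidation and ketogenesis, gluconeogenesis and fasting response, lipogenesis and lipid storage, cholesterol synthesis and uptake, bile acid synthesis and transport, autophagy, lysosome, inflammation and NF-kB, acute phase response, lipid-associated macrophage, extracellular matrix and stellate activation, pericentral hepatocyte genes, periportal hepatocyte genes, circadian clock, glucocorticoid response, NRF2 and xenobiotic response, immediate early and heat shock genes, male-biased and female-biased liver genes, cell cycle, and mitochondrial biogenesis and thermogenic regulators. Shares of nuclei per class were compared with two-sided exact permutation tests over 70 assignments of the libraries, adjusted over 8 classes. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

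Genes were named by a fixed rule. For each hepatocyte comparison these were up to 10 genes in each direction with the largest change among those that passed with libraries that did not overlap, leaving out predicted genes and genes with a mean under 50 counts. If fewer than 3 passed in a direction, the 5 smallest p-values were named as not passing. Becn1, Ass1, Arg1, Fgf21, Ppara and Srebf1 were always named, and up to 4 members of each list were eligible by p-value in the treatment comparison. For regions, and for genes of other classes, up to 5 per direction with the smallest p among those that passed were eligible. List members outside this rule are named as such where they appear.

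The comparisons over both levels, the hepatocyte group contrasts and interaction, the lists, the markers and most alternatives were fixed before the data were examined. Several thresholds for naming clusters, the group contrasts and interactions outside hepatocytes, and the region contrast within Becn1+/+ were added after the data were seen. All contrasts were fitted for genes in hepatocyte-, endothelial-, macrophage- and stellate-like and all nuclei, and 4 for regions in hepatocyte-like nuclei; the other classes were compared by their shares alone, and lists are given where they bear on a paragraph. Alternatives were other scaling (DESeq2 size factors, cyclic loess), no low-count filter, DESeq2, each library left out, regions called in any library, promoter windows, halved counts, doublets removed, a minimum of 3000 counts, Leiden resolution 0.5, thinning to equal totals per library, an offset for the length covered by each library's peaks, and subtraction of expected hepatocyte counts. In counts simulated for 16464 genes with 200 changed, the treatment test over both genotypes recovered 93.9% of genes changed 2-fold, with 6.06% of calls on unchanged genes. The test within Becn1+/+ recovered 89.4%, with 9.68%. Apart from the 200 changes, the simulation gave all libraries the same mean per gene and all groups the same spread. In the measured counts the Becn1+/+ ADI-PEG 20 libraries spread more. These rates need not hold there, and an absence of calls does not show that no gene changed 2-fold. Exploratory fits of the measured counts preceded that simulation. No genome sequence was used, so motif tests and GC correction were not run.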

Results

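Livers of 8 mice on a Western diet gave 3899 to 6231 nuclei per library. Cut-site counts ran from 57662949 to 118077146 per library, with medians of 6994 to 17952 counts per nucleus. The lowest median was in Becn1+/+ ADI-PEG 20 replicate 2 and the highest in Becn1+/+ vehicle replicate 1. Peaks numbered 133237 to 191274 per library and covered 146 to 273 Mb. Becn1+/+ ADI-PEG 20 held both extremes, with the most in replicate 1 and the fewest in replicate 2. Of 23 clusters, 8 were hepatocyte-like, 4 endothelial-like, 2 macrophage-like (1 led by Clec4f, 1 by Mmp12, Itgax and Trem2) and 1 stellate-like. Single clusters were B/plasma-, neutrophil-, cholangiocyte- and erythroid-like, and 4 stayed unnamed. Hepatocyte-like nuclei held 43753555 to 79667685 counts per library and macrophage-like nuclei 3123207 to 10701779. Hepatocyte-like nuclei of the Becn1+/+ ADI-PEG 20 libraries clustered apart: 98.7% of those of replicate 2 were in 1 cluster, and 50.6% and 43.2% of those of replicate 1 in a pair of others. The other libraries shared clusters, with 76.9% of Becn1+/- vehicle replicate 1 in 1 of them.

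The genotype labels were compared first with accessibility at Becn1 itself, which initiates autophagosome formation. In hepatocyte-like nuclei Becn1 had 23.0, 24.6, 25.9 and 30.5 CPM in the Becn1+/+ libraries (mean 26.0 ± 3.23 SD, n = 4) and 27.9, 28.9, 31.4 and 27.2 CPM in the Becn1+/- libraries (28.9 ± 1.80, n = 4). The log2 fold change of Becn1 was 0.16 ± 0.08 (edgeR adjusted p = 0.970), and 53.3% of its counts lie in regions shared with another gene. In endothelial-like nuclei Becn1 had 19.2, 20.2, 17.4 and 18.4 CPM in Becn1+/+ libraries (18.8 ± 1.19). In Becn1+/- libraries it had 31.1, 20.6, 33.2 and 26.4 CPM (27.9 ± 5.62). It was higher on average with 1 allele fewer but did not pass for genotype. Means in Becn1+/+ and Becn1+/- were 23.06 and 24.08 CPM in macrophage-like and 21.88 and 23.39 CPM in stellate-like nuclei. Loss of 1 allele need not change accessibility, so these values do not settle the labels.

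The main question was how ADI-PEG 20 changes hepatocyte chromatin over both genotypes. No gene passed among 16486 in edgeR, with 1866 genes at an unadjusted p under 0.05 (824 by chance), and 118 were called by DESeq2 (38 higher, 80 lower). The gene with the smallest p was Scd1, coding for the desaturase that makes monounsaturated fatty acids (chromosome 19, 44394455 to 44407879, mm10). Scd1 had a log2 fold change of -1.01 ± 0.13 (n = 4 per arm, adjusted p = 0.314), with 185 to 258 CPM in the 4 libraries under ADI-PEG 20 and 398 to 549 CPM in the 4 under vehicle. Other lipogenic genes were lower without passing: Acaca, for fatty acid synthesis, by -0.64 ± 0.13, Acly, for cytosolic acetyl-CoA, by -0.75 ± 0.21 (outside the naming rule, so chosen after its value was seen, as are the other genes so marked), Elovl5 by -0.55 ± 0.11 and Scd2 by -0.59 ± 0.14. Klf9, a transcription factor induced by glucocorticoids, was at 0.52 ± 0.08 (adjusted p = 0.365), from 185 to 269 mean CPM in Becn1+/+ and from 180 to 252 in Becn1+/-.

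Among the other genes with the smallest p were Ide (-0.82 ± 0.14), for the insulin-degrading enzyme, the scavenging chemokine receptor Ackr3 (-0.92 ± 0.16), Glis1 (-0.75 ± 0.13) and Btaf1 (-0.91 ± 0.16, 88.5% of counts shared). On the higher side were Klhdc7b (1.78 ± 0.31), Rhd (0.65 ± 0.11, 67.4% shared), Fbxo31 (0.49 ± 0.09) and Crip2 (0.31 ± 0.06), with all counts of Klhdc7b, Fbxo31 and Crip2 shared with a neighbour. None of these 8 passed. Genes chosen for arginine, stress and lipid control gave 0.22 ± 0.25 for Ass1, which makes argininosuccinate, 0.03 ± 0.23 for Arg1, which splits arginine, -0.02 ± 0.15 for Fgf21, -0.03 ± 0.08 for Ppara and -0.25 ± 0.10 for Srebf1, and none passed. All counts of Arg1, Fgf21, Ppara and Srebf1 are shared with a neighbouring gene. Becn1 was at 0.15 ± 0.08.

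Within Becn1+/+ mice, 414 of 16486 genes passed in hepatocyte-like nuclei, 108 higher and 306 lower under ADI-PEG 20 (3900 at an unadjusted p under 0.05; DESeq2 called 1498). Hexokinase 2 (Hk2), for the first step of glycolysis, fell by 2.66 ± 0.30 on the log2 scale (adjusted p = 0.0165), from 43.5 ± 11.1 to 6.88 ± 0.902 CPM (SD, n = 2). Scd1 fell by 1.15 ± 0.18 (adjusted p = 0.0261) and the secreted peroxidase gene Gpx3 fell by 2.09 ± 0.37 (adjusted p = 0.0372). Mt1 and Mt2, for metal-binding metallothioneins and covered by the same regions, rose by 1.34 ± 0.15 (adjusted p = 0.0149). The cytochrome P450 gene Cyp2c54 rose by 1.42 ± 0.28 (adjusted p = 0.0414), from 4.92 to 13.3 CPM, and Upp2, for uridine breakdown, by 1.28 ± 0.20 (adjusted p = 0.0261), from 216 to 524 CPM.

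Other large rises in Becn1+/+ hepatocyte-like nuclei were the fatty acid hydroxylase gene Cyp4a32 (1.36 ± 0.24), Cdh10 (1.18 ± 0.20), Vmn2r93 (1.08 ± 0.16) and Adgrg7 (1.03 ± 0.16). Klhdc7b was at 2.09 ± 0.43 (adjusted p = 0.0490, all counts shared) but at -0.80 with an offset for covered length, and it no longer passed without Becn1+/+ vehicle replicate 1 or 2 (0.123 and 0.296), Becn1+/+ ADI-PEG 20 replicate 1 or 2 (0.0541 and 0.0604) or Becn1+/- vehicle replicate 1 or 2 (0.101 and 0.101), nor under most other settings. The other largest falls were Pkd1l1 (-2.30 ± 0.40), Pirb (-2.06 ± 0.39), Dnah9 (-1.86 ± 0.38), Fndc10 (-1.84 ± 0.37), the collagen cross-linking gene Loxl2 (-1.76 ± 0.36), Fam81b (-1.75 ± 0.33), the ephrin receptor gene Ephb2 (-1.74 ± 0.23) and Prss27 (-1.67 ± 0.31). Srebf1 was at -0.44 ± 0.10 (adjusted p = 0.0567), Acly at -1.07 and the bile acid transporter gene Slco1a1 at 2.52 ± 0.59 (adjusted p = 0.0737), none of which passed. The 414 calls rest on the vehicle libraries and on the model: 79 were called without Becn1+/+ vehicle replicate 1, 0 without replicate 2, 2981 without Becn1+/+ ADI-PEG 20 replicate 1 and 2 in a fit of the 4 compared libraries alone. Without 1 Becn1+/- library the count was 24 (vehicle replicate 1), 24 (vehicle replicate 2), 154 (ADI-PEG 20 replicate 1) and 153 (ADI-PEG 20 replicate 2), and with an offset for the length that each library's peaks covered it was 1.

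Within Becn1+/- mice, no hepatocyte gene passed (995 at an unadjusted p under 0.05; DESeq2 called 19). The smallest p-values included Scd1 at -0.88 ± 0.18, Klf9 at 0.49 ± 0.11, Ackr3 at -1.08, Btaf1 at -1.09 ± 0.23, Fgfbp3 at -0.89 (76.2% of counts shared) and Myh4 at -0.87, all with an adjusted p of 0.773. On the higher side were also Aprt (0.49), Crip2 (0.37) and Zfp36l2 (0.34), at the same adjusted p. Tmem121b was at 6.34 ± 0.74 (adjusted p = 0.201) from a mean of 61.2 counts per library and 0.00929 CPM in the Becn1+/- vehicle group, so its fold depends on the prior count. Whether the response differed between genotypes was tested as an interaction, in which no hepatocyte gene passed (edgeR, lowest adjusted p = 0.0785; 2728 at an unadjusted p under 0.05; DESeq2 called 486). Among the smallest interaction p-values were those for Ccdc120 (1.99 ± 0.24), Gprc5b (1.01 ± 0.13), the annexin gene Anxa2 (1.00 ± 0.14), Col16a1 (1.21), Itgb4 (0.86), G6pc2 (-1.19 ± 0.15), Sdc2 (-0.67) and Pfkfb1 (-0.76). For Scd1 the interaction was 0.27 ± 0.26. Leaving out Becn1+/+ ADI-PEG 20 replicate 1 gave 962 interaction genes, leaving out replicate 2 gave 37, and leaving out Becn1+/- ADI-PEG 20 replicate 1 gave 1.

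**Figure D1:**
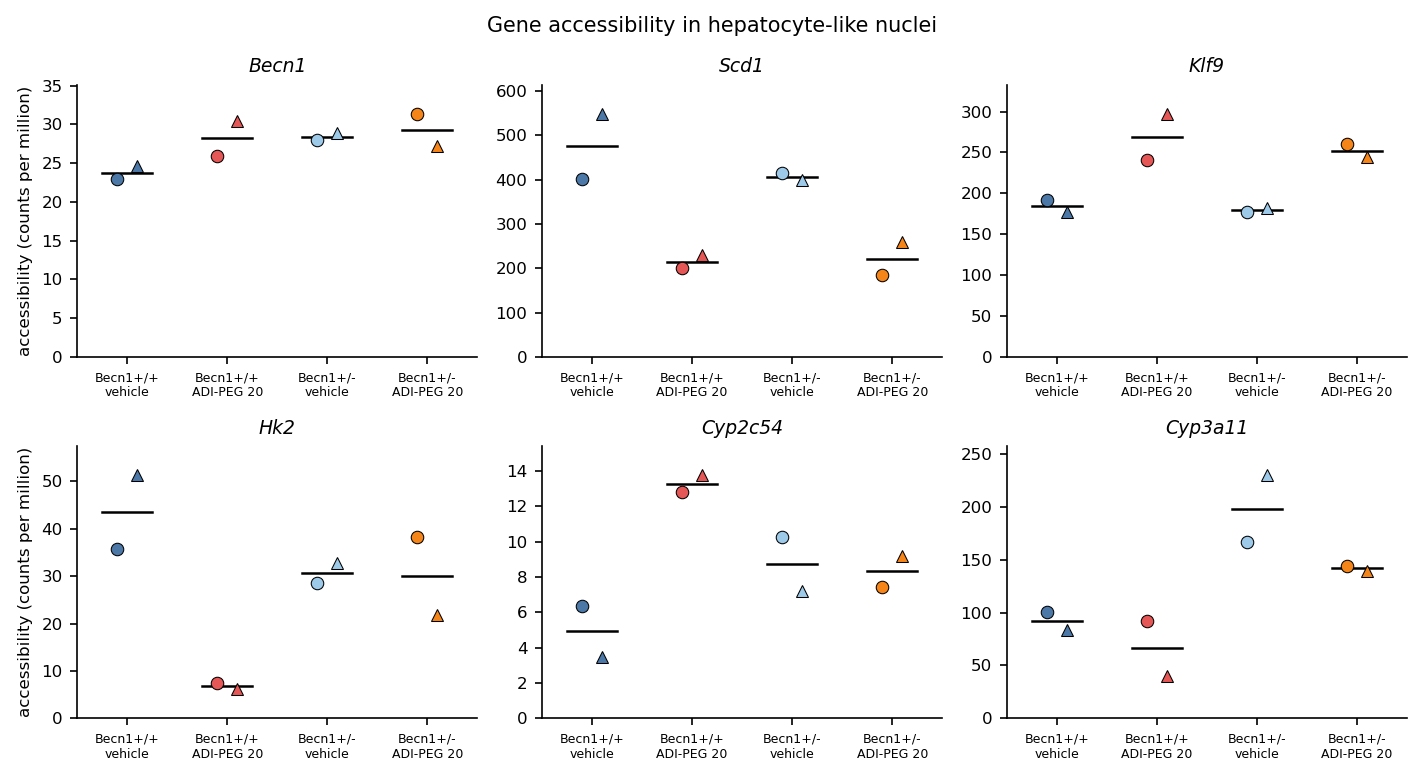
Accessibility in hepatocyte-like nuclei (CPM, axes from 0) of Becn1, Scd1, Klf9, Hk2, Cyp2c54 and Cyp3a11 in the 4 groups, with a circle for replicate 1, a triangle for replicate 2 and a black line for the group mean. Scd1 averaged 476 and 407 CPM in the vehicle groups and 215 and 222 CPM in the ADI-PEG 20 groups, and Hk2 averaged 6.88 CPM in Becn1+/+ ADI-PEG 20 mice.

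The effect of the Becn1+/- genotype on hepatocyte-like nuclei was asked over both treatments and within each. Over both, no gene passed (569 at an unadjusted p under 0.05; DESeq2 called 13, all higher). The drug-metabolising cytochrome gene Cyp3a11 was at 1.10 ± 0.22 (adjusted p = 0.970), with group means of 92.1 and 66.5 CPM in Becn1+/+ and 198 and 142 CPM in Becn1+/-. Next were the glycolytic gene Pgk1 (0.38 ± 0.08), the retinol carrier gene Rbp4 (0.27), Ffar4 (0.27) and the hepatic uptake transporter gene Slco1b2 (0.36 ± 0.08). On the lower side were Krt222 (-1.12 ± 0.22), Arhgap29 (-0.33), Serpinb8 (-0.37), Dnmt3b (-0.30) and Serpina16 (-0.60). Under vehicle no gene passed (623 at an unadjusted p under 0.05; DESeq2 called 29). The lowest adjusted p, 0.0512, was for Tmem121b at -7.11 ± 0.70, again near 0 counts in Becn1+/- vehicle. Eif6, BC029722 and Fam83c, which share regions, were at -0.65 and Col16a1 at -0.56. On the higher side were Brca2 (0.60 ± 0.11), Upp2 (0.94 ± 0.20), the tryptophan dioxygenase gene Tdo2 (0.89 ± 0.19), Cyp3a13 (0.51) and Dkk4 (0.49).

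Under ADI-PEG 20, 16 hepatocyte genes differed by genotype, 13 higher and 3 lower in Becn1+/- (3138 at an unadjusted p under 0.05; DESeq2 called 850). Ccdc120 was higher by 1.61 ± 0.17, Gprc5b by 0.89 ± 0.09, and Anxa2, for a membrane-binding annexin, by 0.73 ± 0.10 (adjusted p = 0.0372, 0.0372 and 0.0434). Also higher were Scgb2b3 (1.46), Dpp7 and Uap1l1 (both 1.24 ± 0.14, shared regions), Slc35f2 (0.85), Xpc (0.83, 92.7% shared), Mafk (0.77, all shared) and Ttc39a (0.75). Among the lower genes were G6pc2 (-1.05 ± 0.11, all counts shared) and, outside the naming rule, Gm14226 (-1.26). Mt1 and Mt2 were at -1.04 ± 0.15 (adjusted p = 0.0597) and did not pass. None of the 16 calls was left without Becn1+/+ vehicle replicate 1 or 2 or Becn1+/- ADI-PEG 20 replicate 1 or 2, where 0 genes were called, nor in the 4 compared libraries alone (0). The count was 4 without either Becn1+/- vehicle library, 1341 without Becn1+/+ ADI-PEG 20 replicate 1 and 405 without replicate 2.

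Single regions were compared in hepatocyte-like nuclei to place the differences. None of 86525 regions passed for treatment over both genotypes (8404 at an unadjusted p under 0.05; DESeq2 called 363), for genotype (3335; 39) or for the interaction (8159; 822). Within Becn1+/+, 177 passed, 10 higher and 167 lower under ADI-PEG 20 (13864; 3994), while an offset for covered length called 508, of which 69 were among the 177. Of the 177, 103 overlapped a gene and 22 lay within 2 kb of a transcription start. The higher regions included the Mt1 and Mt2 locus (chromosome 8, 94170689 to 94185008; 1.31 ± 0.15) and regions in Vezt (chromosome 10, 93943957 to 93948033; 1.02 ± 0.13), 14379 bp from the start of Pik3ap1 (chromosome 19, 41399481 to 41401214; 1.97 ± 0.25) and 13862 bp from that of Wsb1 (chromosome 11, 79268533 to 79270626; 2.01 ± 0.26). A region in Kcnn2 (chromosome 18, 45587063 to 45593440) was at 0.0126 and 0.0625 CPM under vehicle and 10.3 and 6.16 under ADI-PEG 20 in Becn1+/+, and the other way in Becn1+/-, at 1.83 and 2.61 CPM under vehicle and 0.0817 and 0 under ADI-PEG 20. The Vezt region also went the other way in Becn1+/-, with 19.6 and 19.8 CPM under vehicle and 11.9 and 11.8 under ADI-PEG 20. Neither region passed in the interaction.

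The lower regions in Becn1+/+ lay in Nid1, for a basement membrane protein (chromosome 13, 13470921 to 13473606; -1.95 ± 0.16), at the start of Anxa2 (chromosome 9, 69452209 to 69460913; -1.28 ± 0.11), 196941 bp from Ednra (chromosome 8, 77921405 to 77922572; -1.82 ± 0.16), 14196 bp from the kinase gene Sik1 (chromosome 17, 31870000 to 31875601; -1.06 ± 0.09) and in Kif1b (chromosome 4, 149176243 to 149181246; -1.50 ± 0.14). Each of these 5 had an adjusted p of 0.0324. No region was called when any of 6 of the libraries was left out (0), all but the pair of Becn1+/+ ADI-PEG 20: 11389 were called without replicate 1 and 579 without replicate 2.

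The gene lists asked which groups of genes moved together in hepatocyte-like nuclei. For ADI-PEG 20 over both genotypes, lipogenesis and lipid storage had a median of -0.22 over 32 genes (camera adjusted p = 2.02e-07; adjusted p = 0.614 with an estimated correlation); 0 members passed over all genes and 9 were lower adjusted over the list alone. Glucocorticoid response (0.13; camera adjusted p = 0.0223), male-biased (0.21; 0.0286), periportal (0.14; 0.0367), and NRF2 and xenobiotic genes (-0.11; 0.0237) also passed camera, with adjusted p = 0.614, 0.614, 0.631 and 0.614 with an estimated correlation. List means per library are given as mean log2 CPM of the members minus the mean of the Becn1+/+ vehicle libraries. Under ADI-PEG 20 the periportal means per library were -0.00509 and 0.493 in Becn1+/+ and 0.218 and 0.0130 in Becn1+/-. The NRF2 means were -0.0400, -0.242, -0.0289 and 0.0252 in the same order, so Becn1+/+ ADI-PEG 20 replicate 2 carries much of both. In Becn1+/- the glucocorticoid means were 0.245 and 0.1375 under vehicle and 0.3977 and 0.006034 under ADI-PEG 20. The male-biased means there were 0.2812 and 0.09779 under vehicle and 0.1532 and 0.273 under ADI-PEG 20. The treatments thus overlapped within Becn1+/- for both lists. Within Becn1+/+ the lipogenesis median was -0.44, with 30 of 32 genes lower (camera adjusted p = 4.53e-08; adjusted p = 0.497 with an estimated correlation). Of these, 19 were lower adjusted over the list alone and 3 over all genes: Scd1 and, outside the naming rule, the glycerolipid acyltransferase genes Gpam (-0.79 ± 0.15) and Agpat2 (-0.54 ± 0.09). Over the 7 hepatocyte contrasts camera called 39 lists at the preset correlation, 0 with an estimated correlation and 0 by fry for a shared direction. In the Becn1+/+ contrast fry's test for change in either direction reached an adjusted p of 0.0015.

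Other lists that passed camera within Becn1+/+ were glucocorticoid response (median 0.39; 3 higher, 4 adjusted over the list alone; Klf9 0.54 ± 0.11, Mt1 and Mt2; adjusted p = 0.579 with an estimated correlation) and male-biased genes (0.35; 1 higher, 7 adjusted over the list alone). Bile acid genes were at 0.18 (2 higher, 5 adjusted over the list alone: Cyp7b1, which shapes bile acids, 0.63 ± 0.10, and, outside the rule, the exporter Abcb11, 0.45 ± 0.09) and acute phase genes at 0.25 (0 passed, 8 higher and 3 lower adjusted over the list alone). Lipid-associated macrophage genes were at -0.26 (2 lower, Anxa2 -1.19 ± 0.10 and Spp1 -0.88 ± 0.13, and 4 adjusted over the list alone). Immediate early genes were at -0.17 (Klf4 -0.54 ± 0.10 lower; 4 adjusted over the list alone), NRF2 genes at -0.10 (0; 7 lower adjusted over the list alone) and lysosome genes at -0.09 (0; 1 lower adjusted over the list alone), each of the lists from male-biased to lysosome genes with adjusted p = 0.497 with an estimated correlation. The periportal list was at 0.26 (Fbp1, for gluconeogenesis, -0.62 ± 0.10, all counts shared, and adjusted p = 0.961 by camera with an estimated correlation). Its means relative to Becn1+/+ vehicle were -0.122 and 0.122 under vehicle and -0.00509 and 0.493 under ADI-PEG 20, so the difference rests on replicate 2. The values of the vehicle pair mirror each other because that pair is the reference. The NRF2 means, at 0.0273 and -0.0273 under vehicle and -0.0400 and -0.242 under ADI-PEG 20, rest mostly on replicate 2 as well.

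Lists that did not pass camera in that contrast had medians of 0.11 for the urea cycle and arginine metabolism (0 of 28 passed), -0.04 for the integrated stress response (0 of 29), -0.02 for fatty acid oxidation (0 of 32), 0.10 for gluconeogenesis (Fbp1), and -0.10 for cholesterol synthesis (the sterol enzyme gene Nsdhl, -0.51 ± 0.11). They were -0.01 for autophagy (Atg12, for autophagosome elongation, 0.70 ± 0.13, all counts shared) and -0.02 for inflammation (Il1r1 0.95 ± 0.16 and, outside the rule, Tlr4 0.93 ± 0.19). The medians were -0.01 for extracellular matrix (Loxl2), -0.02 for pericentral, -0.04 for circadian, 0.03 for female-biased, 0.00 for cell cycle and 0.01 for mitochondrial regulators (Ucp2, outside the rule, -0.77 ± 0.16). The mean differed in sign from the median for the integrated stress response, fatty acid oxidation, autophagy, inflammation, pericentral and mitochondrial lists. The direction of camera was that of the mean for fatty acid oxidation, autophagy and inflammation and that of the median for the other 3.

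In the remaining hepatocyte contrasts the camera calls were as follows, each with adjusted p of 0.593 to 0.773 with an estimated correlation and 0 members passing. For treatment within Becn1+/- they were lysosome (0.09), immediate early (0.09), female-biased (-0.11) and extracellular matrix genes (-0.12). For genotype over both treatments they were fatty acid oxidation (0.08), lipogenesis (0.07), autophagy (0.06) and NRF2 genes (0.06), and under vehicle male-biased (0.24), bile acid (0.11), glucocorticoid (0.09) and lipid-associated macrophage genes (-0.22). Under ADI-PEG 20 they were lipogenesis (0.25), immediate early (0.17), lysosome (0.16), fatty acid oxidation (0.15) and NRF2 genes (0.06). For the interaction they were lipid-associated macrophage (0.36), lipogenesis (0.32), immediate early (0.23), lysosome (0.17), bile acid (-0.15), glucocorticoid (-0.19) and male-biased genes (-0.32).

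Counts summed over all nuclei were compared because they do not rest on the clustering, although cell composition moves with them. Within Becn1+/+ the share of hepatocyte-like nuclei went from 36.4% to 55.6% and that of macrophage-like nuclei from 14.1% to 9.15%. No gene among 16556 passed for treatment over both genotypes (2382 at an unadjusted p under 0.05; DESeq2 called 269), genotype (311; 1), treatment within Becn1+/- (735; 14), genotype under vehicle (605; 29), genotype under ADI-PEG 20 (3144; 808) or the interaction (3030; 729). Within Becn1+/+, 1148 genes passed, 527 higher and 621 lower (4977; DESeq2 3010). Mt1 and Mt2 rose by 1.15 ± 0.11, Agtr1a, for an angiotensin receptor, by 0.61 ± 0.08 and Upp2 by 1.39 ± 0.18. The desaturase gene Scd4 was at -3.08 ± 0.29, Anxa2 at -0.99 ± 0.09, Gprc5b at -0.90, Lgals1 at -0.81 and Fam129b at -0.76. Without Becn1+/+ vehicle replicate 2 the count was 0, without the Becn1+/- vehicle libraries 327 and 277, and without the Becn1+/- ADI-PEG 20 libraries 21 and 20. Without Becn1+/+ ADI-PEG 20 replicate 1, 273 genes were called for genotype under ADI-PEG 20 and 107 for the interaction.

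Macrophage-like nuclei, the Clec4f-led and Trem2-led clusters summed together, were compared in the same way. No gene among 15561 passed over both genotypes for treatment (825 at an unadjusted p under 0.05; DESeq2 0) or genotype (438; 0), and none within Becn1+/- (1048; 8) or between genotypes under vehicle (751; 5). Within Becn1+/+, 615 genes passed, 237 higher and 378 lower (3029; 735). With an offset for covered length 150 passed, 116 of them among the 615. Fam20c, for a secretory pathway kinase, fell by 1.69 ± 0.15 (adjusted p = 7.76e-05), from 89.0 to 27.3 CPM, and Slc7a11, for cystine uptake, fell by 2.57 ± 0.24 (adjusted p = 0.000113), with 43.1 and 56.8 CPM under vehicle and 7.47 and 9.12 CPM under ADI-PEG 20. The leptin receptor gene Lepr rose by 1.62 ± 0.19 (adjusted p = 0.000667), from 21.6 to 66.5 CPM. Further rises were Adarb2 (1.53 ± 0.22), Tshz2 (0.98 ± 0.14) and the phosphatase gene Ptprm (0.96 ± 0.14), and further falls Scd4 (-3.42 ± 0.38), Mef2c (-1.24 ± 0.15) and Cyth4 (-1.12 ± 0.12, but 0.41 with an offset for covered length).

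The treatment response of macrophage-like nuclei differed between genotypes at 347 genes by the interaction test, 169 with a positive and 178 with a negative interaction (2926 at an unadjusted p under 0.05; DESeq2 called 566). With the offset for covered length 44 passed, 40 of them among the 347. Fam20c had an interaction of 1.97 ± 0.21 (adjusted p = 0.000674), Slc7a11 of 2.67 ± 0.32 (adjusted p = 0.00170) and the adhesion molecule gene Alcam of 1.82 ± 0.24 (adjusted p = 0.00260), with Stra6l (1.56) and Gramd4 (1.47 ± 0.20). Lepr was at -2.30 ± 0.27 (adjusted p = 0.00170), Adarb2 at -2.16 ± 0.31, Tshz2 at -1.51, Ptprm at -1.45 ± 0.19 and C18orf63 at -1.34. The 169 positive genes had a median log2 fold change of -0.65 within Becn1+/+ and 0.23 within Becn1+/-, and the 178 negative genes 0.80 and -0.43. Selection by the interaction favours such opposite medians, and no gene passed within Becn1+/-. Under ADI-PEG 20, 419 genes differed by genotype, 243 higher and 176 lower in Becn1+/- (3022; 611), led by Slc7a11 (2.18 ± 0.25), Fam20c (1.31 ± 0.16), and Gipc3 (0.90), Hmg20b and Mfsd12 (0.91), whose regions are shared. Lower in Becn1+/- were Tnk2 (-1.14), Grm5 (-1.03), Ptprm (-0.92), Epn2 (-0.90) and Glra3 (-1.36).

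Of 16 lipid-associated macrophage genes, 9 were lower within Becn1+/+ (11 adjusted over the list alone; median -0.56; camera adjusted p = 1.22e-06; adjusted p = 0.435 with an estimated correlation; fry adjusted p = 0.0299). By rule these included Anxa2 (-1.25 ± 0.16) and the actin-capping gene Capg (-0.81 ± 0.13), and outside it the lysosomal glycoprotein gene Gpnmb (-2.91 ± 0.33). In the interaction 4 were higher (8 adjusted over the list alone; adjusted p = 0.571 with an estimated correlation). Of 32 lysosome genes, 6 were lower within Becn1+/+ (7 adjusted over the list alone) and 4 were higher in the interaction (8), among them, outside the rule, Ctsd (0.72 ± 0.17) and Psap (0.66 ± 0.15). Itgax and Mmp12 were also among the 9, but with Trem2 they define 1 of the 2 clusters. That cluster held 52.8% and 49.1% of macrophage-like nuclei in Becn1+/+ vehicle, 4.49% and 4.62% in Becn1+/+ ADI-PEG 20, 16.0% and 38.6% in Becn1+/- vehicle and 29.6% and 36.8% in Becn1+/- ADI-PEG 20. Within the Clec4f-led cluster alone 26 interaction genes and 23 genes within Becn1+/+ passed, Lepr (-1.57) and Ptprm (-1.06) among the interaction genes but not Fam20c (1.14; adjusted p = 0.141) or Slc7a11 (2.35; 0.0537). Leaving out 1 library moved the 347 interaction genes to 176 and 88 (Becn1+/+ vehicle replicates 1 and 2), 1230 (Becn1+/+ ADI-PEG 20 replicate 2), 61 (Becn1+/- vehicle replicate 1), and 99 and 130 (Becn1+/- ADI-PEG 20 replicates 1 and 2). It moved the 615 genes to 241 and 70 without Becn1+/+ vehicle replicates 1 and 2 and to 1129 without Becn1+/+ ADI-PEG 20 replicate 2. The 419 genes became 250 and 248 without the Becn1+/+ vehicle libraries, 247 and 1166 without Becn1+/+ ADI-PEG 20 replicates 1 and 2, and 30 and 58 without the Becn1+/- ADI-PEG 20 libraries.

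**Figure D2:**
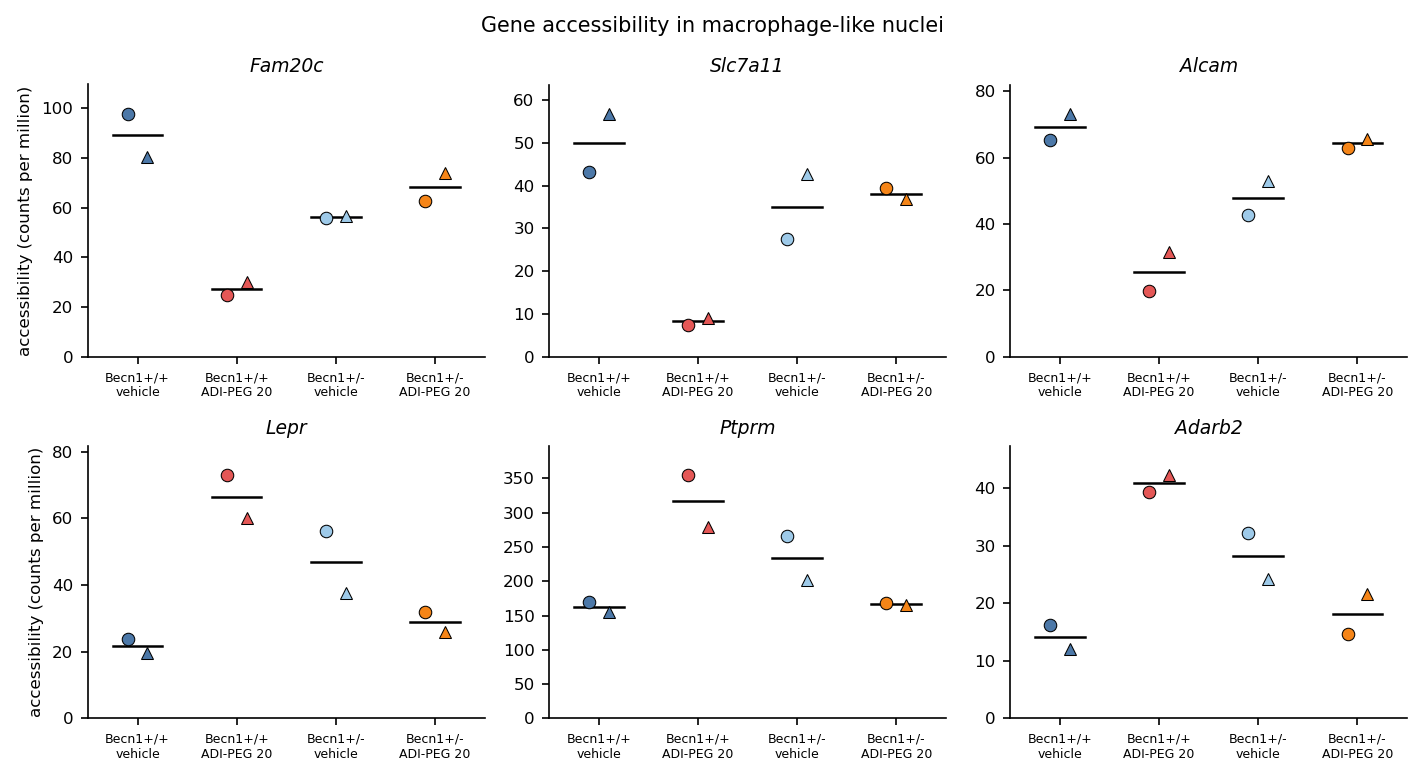
Accessibility in macrophage-like nuclei (CPM, axes from 0) of Fam20c, Slc7a11, Alcam, Lepr, Ptprm and Adarb2 in the 4 groups, with a circle for replicate 1, a triangle for replicate 2 and a black line for the group mean. Fam20c averaged 89.0, 27.3, 56.3 and 68.3 CPM and Lepr 21.6, 66.5, 46.9 and 28.9 CPM in Becn1+/+ vehicle, Becn1+/+ ADI-PEG 20, Becn1+/- vehicle and Becn1+/- ADI-PEG 20.

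In endothelial-like nuclei 1 of 15637 genes passed for treatment over both genotypes, Btaf1, for a TBP-associated factor, at -0.73 ± 0.10 (adjusted p = 0.0178; 88.5% of counts shared), and the same gene passed within Becn1+/- (-0.88 ± 0.13, adjusted p = 0.0494). For genotype 2 genes were lower, Fam83d, for a spindle protein (-0.62 ± 0.09, adjusted p = 0.0356), and a predicted gene. Within Becn1+/+ 13 genes passed. Of these 7 were higher, with Sdsl (1.34 ± 0.21) and Sds (1.32) in shared regions, Adh7 (1.41 ± 0.25), Prkag3 (0.99) and Sec14l5 (0.77). The 6 lower genes included Flrt2 (-1.02 ± 0.15), the leukocyte adhesion gene Selp (-0.67 ± 0.11), Cst13 (-1.56), Tbx5 (-1.19) and Sh3bgrl2 (-0.81). No gene passed for genotype under vehicle (482 at an unadjusted p under 0.05; DESeq2 1), under ADI-PEG 20 (1968; 25) or for the interaction (1663; 23). The call of Btaf1 over both genotypes ended without Becn1+/+ vehicle replicate 1 (adjusted p = 0.167), Becn1+/- vehicle replicate 1 or 2 (0.0779 and 0.245) or Becn1+/- ADI-PEG 20 replicate 1 or 2 (0.0803 and 0.156). The 13 genes became 0 without either Becn1+/+ vehicle or either Becn1+/- ADI-PEG 20 library, 2 without either Becn1+/- vehicle library and 786 and 482 without the Becn1+/+ ADI-PEG 20 libraries. The call of Fam83d ended without any 1 library (adjusted p = 0.0734 to 0.731) but Becn1+/+ ADI-PEG 20 replicate 1 (0.0136).

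In stellate-like nuclei no gene among 15150 passed for treatment (961 at an unadjusted p under 0.05; DESeq2 3) or genotype (473; 0), for treatment within Becn1+/- (651; 0) or for genotype under vehicle (620; 0) or ADI-PEG 20 (1427; 1). Within Becn1+/+ 71 passed, 23 higher and 48 lower (1995; 57). Higher were Tat, for tyrosine breakdown, at 3.68 ± 0.61 from 27.5 counts per library (adjusted p = 0.145 and 0.192 without Becn1+/+ vehicle replicates 1 and 2), Ass1 at 1.03 ± 0.20, Rapgef4 at 0.71, and Acox2 and Kctd6 at 0.81 (shared regions). Lower were the smooth muscle tropomyosin gene Tpm1 at -0.76 ± 0.13, the collagen gene Col1a1 at -0.91 ± 0.21, S1pr2 at -0.89, Samd14 at -1.02 ± 0.16 (all counts shared), Fam129b at -0.75 and Rem1 at -4.30 ± 0.70. The interaction passed at 9 genes. It was positive for 6, with Ptger1 (1.39 ± 0.23, shared), Rem1 (4.64), Gas7 (1.58), Ttyh3 (1.31) and Vwce (1.70), and negative for 3, Pcdh9 (-1.57), Dpyd (-2.23) and Crybg1 (-1.33). Without Becn1+/+ vehicle replicates 1 and 2 the 71 genes became 2 and 1, without the Becn1+/+ ADI-PEG 20 libraries 358 and 277, and without the Becn1+/- ADI-PEG 20 libraries 21 and 18. The 9 became 2 and 1 without the Becn1+/+ vehicle libraries, 120 and 181 without the Becn1+/+ ADI-PEG 20 libraries, and 0 without Becn1+/- vehicle replicate 1 or either Becn1+/- ADI-PEG 20 library.

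Hepatocyte genes such as Sds, Sdsl, Tat and Ass1 were higher in Becn1+/+ endothelial- or stellate-like nuclei together with the summed hepatocyte markers. Between Becn1+/+ vehicle and ADI-PEG 20 the markers went from 606 to 924 CPM in endothelial-like, 530 to 795 in stellate-like, and 5736 to 7862 in hepatocyte-like nuclei. In macrophage-like nuclei they were at 383 and 320 CPM under vehicle and at 304 and 587 under ADI-PEG 20, so only replicate 2 lay above the vehicle libraries. Of the lists in endothelial-like nuclei within Becn1+/+, periportal genes had a median of 0.62 (2 higher, 7 adjusted over the list alone; adjusted p = 0.389 with an estimated correlation) and bile acid genes of 0.34 (1 higher, 12 adjusted over the list alone; 0.389). In stellate-like nuclei bile acid genes were at 0.47 (1 higher, 11 adjusted over the list alone; 0.623) and extracellular matrix genes at -0.22 (1 lower, 2 adjusted over the list alone; 0.623).

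The cell composition was compared as shares of nuclei per library. Hepatocyte-like nuclei made up 49.8% ± 7.96 (SD, n = 4) under ADI-PEG 20 and 39.0% ± 6.65 under vehicle (exact p = 0.0857, adjusted 0.183). Endothelial-like nuclei made up 16.7% ± 2.34 and 21.3% ± 2.29 (exact p = 0.0286, the smallest possible, adjusted 0.183). Macrophage-like nuclei made up 10.2% ± 1.38 and 13.4% ± 2.68 (exact p = 0.0571, adjusted 0.183), and stellate-like nuclei 8.47% and 7.62% (exact p = 0.114). No class passed after adjustment, but with a smallest possible p of 0.0286 over 8 classes a change in 1 class alone could not have passed, so this does not show that shares stayed the same. Without Becn1+/+ vehicle replicate 2 the macrophage difference went from -3.24 to -1.99 points, without Becn1+/+ ADI-PEG 20 replicate 1 the hepatocyte difference from 10.8 to 7.18, and without Becn1+/+ ADI-PEG 20 replicate 2 the stellate difference from 0.855 to 0.501. With at least 3000 counts per nucleus the stellate difference was 0.245. The neutrophil difference of -0.215 points was 0.0322 without Becn1+/+ ADI-PEG 20 replicate 1 and -0.572 without Becn1+/- ADI-PEG 20 replicate 2. Shares of B/plasma- (1.38% and 1.74%), neutrophil- (1.05% and 1.26%) and cholangiocyte-like nuclei (0.653% and 1.04%) did not pass either. The B/plasma difference of -0.366 points was -0.592 without Becn1+/+ ADI-PEG 20 replicate 2 and -0.115 without Becn1+/- vehicle replicate 2. In the Becn1+/- ADI-PEG 20 libraries there were 29 and 40 erythroid-like nuclei, against at most 5 elsewhere. Between genotypes the adjusted exact p was 1 for every class, with 42.8% hepatocyte-like nuclei in Becn1+/- and 46.0% in Becn1+/+. That difference of -3.17 points was -8.59 without Becn1+/+ vehicle replicate 2 and 1.73 without Becn1+/+ ADI-PEG 20 replicate 1. The unnamed clusters are given in the order Becn1+/+ vehicle, Becn1+/+ ADI-PEG 20, Becn1+/- vehicle and Becn1+/- ADI-PEG 20. Cluster 6, shallow and nearest to macrophages, held 7.01%, 4.52%, 7.55% and 8.68% of nuclei. Cluster 13, between dendritic cells and macrophages, held 3.99%, 1.72%, 3.12% and 3.21%. Cluster 16, shallow and nearest to T and NK cells, held 3.09%, 1.72%, 2.28% and 1.90%. Cluster 21, like simulated doublets, held 0.931%, 0.205%, 1.15% and 1.03%.

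**Figure D3:**
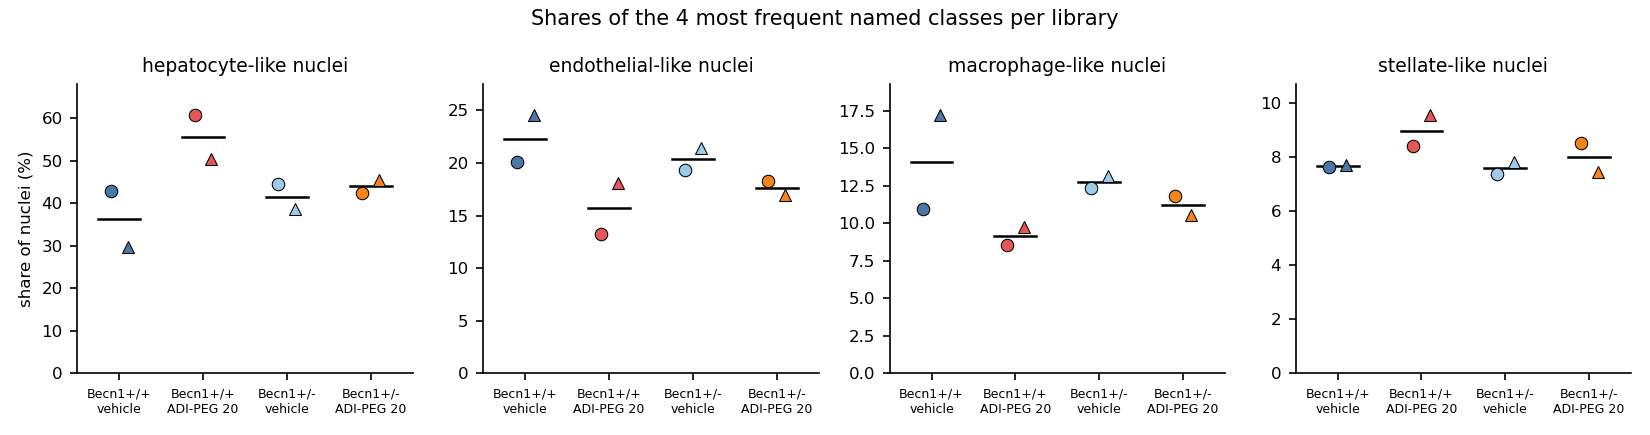
Share of nuclei (% of each library) in the 4 most frequent named classes, hepatocyte-, endothelial-, macrophage- and stellate-like, for the 4 groups. A circle marks replicate 1, a triangle replicate 2 and a black line the group mean. Hepatocyte-like nuclei averaged 36.4%, 55.6%, 41.6% and 44.0% in Becn1+/+ vehicle, Becn1+/+ ADI-PEG 20, Becn1+/- vehicle and Becn1+/- ADI-PEG 20.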

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

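Of the tests here, those of the cluster mix and of depth were chosen after the result was seen, and the contrast itself was picked out after all fitted combinations of class and contrast had been looked at.

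The interaction of treatment and genotype passed at 347 genes in macrophage-like nuclei, with Fam20c, Slc7a11 and Alcam lower under ADI-PEG 20 in Becn1+/+ against Becn1+/- and Lepr, Ptprm, Adarb2 and Tshz2 higher. Against a change in the mix of Clec4f-led and Trem2-led nuclei as the whole cause, the genes kept a median of 78.97% of their interaction within the Clec4f-led cluster (interquartile range 65.57% to 89.67%; 346 of 346 with the same sign); only 26 passed there, as the median size went from 1.021 to 0.8041 and the median SE from 0.2095 to 0.2389. Against a difference in total counts, 71.18% of the genes passed again after thinning to equal totals. Thinning leaves the peaks as called and depth per nucleus as it was. The medians were 16014 and 13015.5 counts in Becn1+/+ vehicle and 8640 and 6280 in Becn1+/+ ADI-PEG 20. In Becn1+/- they were 6940 and 13894.5 under vehicle and 8606 and 8621 under ADI-PEG 20. Against hepatocyte DNA, 98.82% of the positive and 96.63% of the negative genes passed again after the expected hepatocyte counts were subtracted. A first test went with hepatocyte DNA (the interaction of 15 hepatocyte markers had quartiles of -0.8657 and -0.3695), and the subtraction was devised after that result. Peak calls of different extent cannot be told apart from the pattern: 71.76% of the genes kept at least 50% of their size with the covered-length offset, but this bound, set in advance, does not settle it, because the median size fell to 0.6745 while the median SE rose from 0.2101 to 0.2475, 44 genes passed (40 of the 347 among them), and peak extent itself follows accessibility. The cluster mix stays open as a part of the cause. The Trem2-led share went from 52.8% and 49.1% to 4.49% and 4.62% under ADI-PEG 20 in Becn1+/+. In Becn1+/- it went from 16.0% and 38.6% to 29.6% and 36.8%. The clusters were cut from the same accessibility data, so a fit within the Clec4f-led cluster cannot remove a shift inside it. Peak extent, depth per nucleus and chance stay open too, the last since the contrast was picked out from many. Also open, and untested, is the hypothesis of a macrophage response to ADI-PEG 20 that depends on Becn1. More animals per group, with peaks called on all libraries together, would test it.

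In stellate-like nuclei the response to ADI-PEG 20 differed between genotypes by the same test at 9 genes, among them Rem1, Ptger1 and Pcdh9. Without Becn1+/+ vehicle replicates 1 and 2 the count was 2 and 1, without Becn1+/+ ADI-PEG 20 replicates 1 and 2 it was 120 and 181, and without Becn1+/- vehicle replicate 1 or either Becn1+/- ADI-PEG 20 library it was 0. A single library lay apart from the others of its group in 3 of 68 groups tested, where chance gives about 1 in 20. Arg1, for the last step of the urea cycle, was at 136.277 CPM in Becn1+/- ADI-PEG 20 replicate 2 and at 196.553 to 200.612 CPM in the other Becn1+/- libraries. Fgf21, for a fasting hormone of the liver, was at 33.6289 CPM in the same library and at 21.9017 to 23.5884 CPM in the other ADI-PEG 20 libraries. Becn1+/+ ADI-PEG 20 replicate 1 had 191274 peaks, where the other ADI-PEG 20 libraries had 133237 to 141664.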

How the results depend on the processing

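Of the alternatives below, 246 of 475 were planned; added after the data were seen were all those of the group contrasts and interactions outside hepatocyte-like nuclei and of the regions within Becn1+/+, and for hepatocyte-like nuclei within Becn1+/+ those of region choice, promoters, doublets, depth and the covered-length offset. Of 475 alternatives to 42 counts, 305 stayed within 1.5 times or at 0, 64 made calls where there were none, 38 ended all calls, 68 moved the count and 0 reversed it. The 305 include every alternative of the share tests, where the count was 0 throughout, so they overstate how stable counts above 0 were. For the named genes the side of the threshold stayed in 5316 cases, 489 no longer passed and 170 newly passed. Direction was compared only where the gene passed in at least 1 of the fits. Changes of sign among genes that passed in neither are therefore not counted. Of the cases compared 2 reversed, both with the covered-length offset. Klhdc7b in hepatocyte-like nuclei within Becn1+/+ went from 2.09 to -0.80. Cyth4 in macrophage-like nuclei within Becn1+/+ went from -1.12 to 0.41. The cause was not tested for any change below unless one is given.

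The DESeq2 Wald test called more genes than edgeR in the contrasts given next, but 57 against 71 in stellate-like nuclei within Becn1+/+ and 2 against 2 for genotype in endothelial-like nuclei. In hepatocyte-like nuclei it called 118 genes for treatment (edgeR 0), 13 for genotype (0), 1498 within Becn1+/+ (414, all of them shared), 19 within Becn1+/- (0), 29 for genotype under vehicle (0), 850 under ADI-PEG 20 (16) and 486 for the interaction (0). In all nuclei the counts were 269, 1, 3010, 14, 29, 808 and 729 in the same order (edgeR 1148 within Becn1+/+, else 0). In endothelial-like nuclei it called 20 for treatment (edgeR 1), 134 within Becn1+/+ (13), 2 within Becn1+/- (1), 1 and 25 for genotype under vehicle and ADI-PEG 20 (0 and 0) and 23 for the interaction (0). In macrophage-like nuclei it called 8 within Becn1+/- and 5 for genotype under vehicle (0 and 0) and 566 for the interaction (347; 344 shared), and in stellate-like nuclei 3 for treatment and 1 for genotype under ADI-PEG 20 (0 and 0). For regions it called 363 for treatment, 39 for genotype, 822 for the interaction (0 each) and 3994 within Becn1+/+ (177).

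With DESeq2 size factors in edgeR, Btaf1 within Becn1+/- endothelial-like nuclei was no longer called (0), and cyclic loess offsets gave 5 hepatocyte genes for genotype under ADI-PEG 20 in place of 16. Fitting only the 4 libraries compared, which leaves fewer libraries to estimate the spread, gave 2 hepatocyte genes within Becn1+/+, 4 within Becn1+/-, 11 for genotype under vehicle and 0 under ADI-PEG 20. Within Becn1+/+ the union of regions called 166 hepatocyte genes (152 shared with the 414) and promoters alone 215 (163 shared, from fewer genes tested). The covered-length offset called 1 hepatocyte gene within Becn1+/+, 150 macrophage genes within Becn1+/+ (116 shared with the 615), 44 for the macrophage interaction, 508 regions within Becn1+/+ (69 shared with the 177) and 1 region for treatment. The Clec4f-led cluster alone, with fewer nuclei, called 23 macrophage genes within Becn1+/+ and 26 for the interaction. Of 39 list calls by camera in hepatocyte-like nuclei 0 held with an estimated correlation and 0 by fry.

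Leaving out 1 library leaves 3 in an arm of the comparisons over both levels, and in the contrasts within a level it leaves a lone sample that is assumed to vary like the other groups. The counts in hepatocyte-like nuclei then ran from 0 to 1 for treatment (1 without Becn1+/+ vehicle replicate 2), 0 to 2981 within Becn1+/+, 0 to 4 for genotype under vehicle (4 without either Becn1+/+ ADI-PEG 20 library), 0 to 1341 under ADI-PEG 20 and 0 to 962 for the interaction, and stayed at 0 for genotype and within Becn1+/-. In all nuclei they ran from 0 to 1524 within Becn1+/+, 0 to 273 for genotype under ADI-PEG 20 and 0 to 107 for the interaction. In endothelial-like nuclei they ran from 0 to 6 for treatment, 0 to 2 for genotype, 0 to 786 within Becn1+/+, 0 to 11 within Becn1+/-, 0 to 6 for genotype under vehicle, 0 to 547 under ADI-PEG 20 and 0 to 319 for the interaction; the 13 genes within Becn1+/+ became 0 without either Becn1+/+ vehicle or either Becn1+/- ADI-PEG 20 library, 2 without either Becn1+/- vehicle library, and 786 and 482 without Becn1+/+ ADI-PEG 20 replicates 1 and 2. The 1 gene for treatment became 6 without Becn1+/+ ADI-PEG 20 replicate 1, and the 1 gene within Becn1+/- became 5 and 11 without Becn1+/+ ADI-PEG 20 replicates 1 and 2 and 0 without either Becn1+/+ vehicle library, Becn1+/- vehicle replicate 1 or either Becn1+/- ADI-PEG 20 library.

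In macrophage-like nuclei they ran from 0 to 2 for treatment, 70 to 1129 within Becn1+/+, 0 to 7 within Becn1+/-, 0 to 4 for genotype under vehicle, 30 to 1166 under ADI-PEG 20 and 61 to 1230 for the interaction. In stellate-like nuclei they ran from 0 to 4 for treatment, 0 to 1 for genotype, 1 to 358 within Becn1+/+, 0 to 6 within Becn1+/-, 0 to 3 and 0 to 159 for genotype under vehicle and ADI-PEG 20 and 0 to 181 for the interaction. The 71 stellate genes within Becn1+/+ became 2 and 1 without Becn1+/+ vehicle replicates 1 and 2, 358 and 277 without the Becn1+/+ ADI-PEG 20 libraries and 21 and 18 without the Becn1+/- ADI-PEG 20 libraries. The 9 interaction genes became 2 and 1 without Becn1+/+ vehicle replicates 1 and 2, 120 and 181 without Becn1+/+ ADI-PEG 20 replicates 1 and 2, and 0 without Becn1+/- vehicle replicate 1 or either Becn1+/- ADI-PEG 20 library. Regions ran from 0 to 1 for treatment, 0 to 4013 for the interaction (4013 and 101 without Becn1+/+ ADI-PEG 20 replicates 1 and 2) and 0 to 11389 within Becn1+/+.

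Of single genes, Scd1 within Becn1+/+ hepatocyte-like nuclei ran from -1.35 to -0.91 and no longer passed without Becn1+/+ vehicle replicate 2 (adjusted p = 0.199), just missed the threshold without Becn1+/+ ADI-PEG 20 replicate 2, and did not pass without Becn1+/- vehicle replicate 1 or 2 (0.0669 and 0.0672), in the 4 libraries compared (0.138) or with the covered-length offset (-1.09; 0.113). Hk2 within Becn1+/+ hepatocyte-like nuclei ran from -2.90 to -1.94 and was the 1 gene that passed with that offset (-1.94; 0.0224), but not without Becn1+/+ vehicle replicate 2 (0.135), without Becn1+/+ ADI-PEG 20 replicate 2 (0.0838) or in the 4 libraries compared (0.0508). No paired analysis was possible because the replicate numbers do not link animals of different groups. A correction in bins of GC content and an analysis of motifs were not run, since both need the genome sequence. Depth limits which genes could be tested: of 16556, the test covered 15637 in endothelial-like, 15561 in macrophage-like and 15150 in stellate-like nuclei.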

Other observations

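Of the tests here, those of depth, macrophage counts and peak extent for the 414 hepatocyte genes were chosen after the result was seen, and the patterns themselves were noticed in the data.

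The hepatocyte genes with the smallest p for ADI-PEG 20 included a pair on chromosome 19, Ide (37268743 to 37337852; -0.82 ± 0.14) and Btaf1 (36926079 to 37012752; -0.91 ± 0.16), with Fgfbp3 next to Btaf1 (36917550 to 36919615) at 104, 74.2, 85.9 and 46.5 CPM in Becn1+/+ vehicle, Becn1+/+ ADI-PEG 20, Becn1+/- vehicle and Becn1+/- ADI-PEG 20. Btaf1 shares 88.5% and Fgfbp3 76.2% of its counts with another gene, and the 3 genes were singled out after their values were seen. Slco1a1, a hepatic uptake transporter gene with a male bias (1.49 ± 0.55), and Hamp, for the iron hormone hepcidin (1.98 ± 0.46, all counts shared), did not pass for treatment in hepatocyte-like nuclei, nor did Cyp2b9 (-1.22 ± 0.31), Cyp1a2 (0.58 ± 0.15) or the stress gene Chac1 (0.38 ± 0.11).

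Within Becn1+/+ hepatocyte-like nuclei 414 genes passed, among them Hk2 and Gpx3 with falls and Mt1, Mt2 and Cyp2c54 with rises. Against a difference in total counts, 92.27% of them passed again after thinning to equal totals. Thinning leaves the peaks as called and depth per nucleus as it was. The medians were 34838 and 34669 counts in Becn1+/+ vehicle and 17529 and 12268 in Becn1+/+ ADI-PEG 20. Fewer macrophage counts cannot be told apart from the falls: the log2 ratio of the summed macrophage markers was 0.03488 where the lower genes had a median of -0.6082, but the markers' level in hepatocyte-like nuclei (848 CPM against 3105 in macrophage-like nuclei) would hide a small share, and the lipid-associated macrophage list was lower there, at -0.26 with Anxa2 and Spp1 passing. Peak calls of different extent went with the gene pattern: 30.92% of the genes kept at least 50% of their log2 fold change with the covered-length offset (median kept 34.42%; 336 with the same sign), and the calls went from 414 to 1 as the median size fell from 0.5907 to 0.2279 and the median SE rose from 0.1031 to 0.1216. In single regions the same offset went the other way, from 177 calls to 508 (69 shared). Since peak extent itself follows accessibility, the offset may remove a real change with a technical one. Peak calling, depth per nucleus, a difference between the animals or in processing and, untested, a response of hepatocytes to ADI-PEG 20 stay open. The fit also shares its estimate of spread over all groups, which may be too small for this one. The SD of log2 ratios between replicates was 0.402 in Becn1+/+ ADI-PEG 20. It was 0.218, 0.211 and 0.242 in Becn1+/+ vehicle, Becn1+/- vehicle and Becn1+/- ADI-PEG 20.

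The 2 Becn1+/+ ADI-PEG 20 libraries lay far apart in hepatocyte-like nuclei, with an SD of log2 ratios of 0.402 and 374 of 15970 genes over 2-fold apart, against 0.218, 0.211 and 0.242 (63, 48 and 103 genes) in Becn1+/+ vehicle, Becn1+/- vehicle and Becn1+/- ADI-PEG 20. Replicates 1 and 2 had 369 and 1144 CPM at Egfr, 40.7 and 182 at Hamp, 97.3 and 24.1 at Ackr4 and 236 and 591 at Mug1. After thinning to equal totals the SD was 0.3992 (highest other pair 0.2437). The totals of this pair were already close, at 44584344 and 43753555 counts, so they explain little of the spread. Depth per nucleus, with medians of 17529 and 12268 counts, was not equalised. Per covered length the SD was 0.347 (highest other 0.2158). This does not settle peak extent, because count ratios had r = 0.7017 with covered-length ratios across genes. In the other classes compared the same division raised the SD (endothelial-like from 0.4127 to 0.465). A different time of day at collection cannot be told apart from the pattern: the clock genes lay at percentile 91.87 of random lists, and the bound set in advance, below the 95th, does not settle it because a narrow miss is no evidence of equal clocks; the periportal, pericentral, lipogenesis and acute phase lists lay at percentile 100. Depth per nucleus, peak extent and the time of day stay open. So does a difference between the animals or their livers, or a step of processing not tested here. The Becn1+/+ ADI-PEG 20 group carries the largest spread of the 4 groups in every class compared (0.413, 0.390 and 0.389 in endothelial-, macrophage- and stellate-like nuclei).

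Other groupings of the libraries were counted for the comparisons of 4 with 4, over 34 groupings that could be fitted. Where 0 genes or regions passed, every grouping calls at least as many (34 of 34), so the count says nothing about chance. This holds for treatment and genotype in hepatocyte-like nuclei (highest other 1 and 0), all nuclei (1 and 16), macrophage-like nuclei (64 and 215), stellate-like nuclei (6 and 31) and for regions (1 and 1). In endothelial-like nuclei 3 of 34 called at least 1 gene for treatment (highest other 2), so chance could not be excluded, and 1 of 34 called 2 for genotype (highest other 1). That margin is 1 gene, with 526 genes at an unadjusted p under 0.05 where chance gives 782, so chance is not taken as excluded there either. The 64 and 215 came from 1 grouping, Becn1+/+ vehicle with Becn1+/- ADI-PEG 20 against the rest, which points to a structure of the samples that neither factor alone describes. It is the sign pattern of the interaction, for which 1 of 100 groupings into 4 pairs called as many as the real 347; the next, with 272, has the same sign pattern with other pairs. As this contrast was picked out after all had been looked at, the count does not exclude chance for it.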
